A study of Mus musculus with 2 samples.

How the data were processed

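Total RNA of mouse embryo brain at embryonic day 10.5 was hybridised to 2 Affymetrix 3' expression arrays, 1 for a sample labelled KO (knockout) and 1 for a sample labelled WT (wild type). Per the labels' protocols, biotinylated cRNA was made from 250 ng of total RNA, and both samples carry the strain label C57BL/6. The labels do not name the gene that was knocked out, the sex of the embryos, or the number of embryos in each sample. Group membership was taken from the sample titles.

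The authors deposited 1 table of linear probe set intensity values, with 45101 probe sets and 1 column per array. Per the submitters' processing notes, the values come from Affymetrix Expression Console. The summary algorithm and its version are not given in the sources used here. In each array the mean intensity without the lowest and the highest 2% of probe sets was 100.0, so both arrays had been brought to a common global scale. Sorted values of the arrays differed, so no quantile normalisation had been applied. The deposited table, as used here, holds no detection calls and no probe-level values. Precision is limited by the number of arrays, since there is 1 per group.

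The plan made before the data were examined took the deposited values for log2 values and held a second course for linear ones, which was followed. Both arrays were scaled to the same median (the medians differed by a factor of 1.001) and values were taken as log2(intensity + 16). The pseudocount of 16 keeps noise near background from dominating, and it understates changes of dim genes. All differences are KO minus WT on this scale. Gene symbols came from the platform annotation supplied with the table. Of the probe sets, 34957 had 1 gene symbol, 920 had several, 9160 were unnamed here and 64 were array controls. Of those with 1 symbol, 34741 were found by Entrez number in a RefSeq gene table of assembly GRCm38.p6, and no symbol changed. Probe sets with several symbols or none named no gene. Each of the 18204 genes was represented by its probe set with the highest mean of both arrays. A gene passed the level filter if its value in the higher array was at or above the median over all named genes, which lies at an intensity of 41.5 after taking off the pseudocount, and 9297 genes passed.

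With 1 array per group no test between groups was possible, and no p-value is given. Genes at least 2-fold apart were counted among those passing the filter. For 43 gene lists the median difference of all measured members was placed among the medians of 10000 random lists of the same size, matched on mean level in 20 bins. A list was said to stand apart when its median fell below the 2.5th or above the 97.5th percentile. The percentile describes these 2 arrays only. It also treats genes as independent, which members of a pathway are not. The spread of the difference between probe sets of 1 gene was used as a measure of probe noise, and it says nothing about animals.

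The 43 lists, the level filter, the 2-fold threshold and the rule for named genes were fixed at that point too. Listed genes with no probe set named here were not analysed here. That rule named the 12 largest rises and 12 largest falls among genes passing the filter, leaving out predicted genes. It also named the leading 4 members of each list that stood apart, all members of the list of Y-linked genes and Xist, and any list member at least 2-fold apart that passed the filter. It gave 67 genes. Other genes in the text, such as further members of the lists, were chosen after their values were seen. A further 4 lists were added after a first look at the data (FGF feedback genes, genes escaping X inactivation, early-stage RNA regulators and later neural genes).

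The procedures were tested on simulated data in which the real differences were permuted within level bins. With no shift, 5.0% of the simulated lists stood apart. That rate follows from permuting within the same level bins as the random lists use. The permutation also removes any joint behaviour of list members, so the rate for real lists was not tested. A shift of 0.1 was found in 65.2% of lists and one of 0.2 in 95.2%, over 18204 genes and 20 simulations. Among 200 changed genes of the 9297, a true shift of 1 passed the 2-fold threshold in 48.0% of cases and a shift of 1.5 in 99.0%. Alternatives covered the scaling (log2 median, quantile, loess on level with a span of 0.3), the level filter, the rule for genes with several probe sets, the pseudocount, a floor on low values, the threshold, and the matching, members and summary of the lists. Where a gene had an even number of probe sets, its median probe set was that with the lower of the middle differences. This setting therefore leans towards lower values in KO. Leaving out the X and Y chromosomes was added later. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.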

Results

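Gene expression was profiled in the brain of mouse embryos at midgestation, when the neural tube is regionalised and the first neurons appear. The design sets 1 KO sample against 1 WT sample to ask which transcripts differ between the genotypes. Each sample has 1 array and there are no replicates, so every difference below is between these 2 arrays and has no replicate error. The gene targeted in the knockout is not named in the labels, so its own signal could not be used to check them. Deposited signals ranged from 0.03 to 5983 in the KO array and from 0.01 to 6549 in the WT array, with medians of 13.2 in both.

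The KO and WT brains had closely similar profiles. Across the 9297 genes passing the level filter, Pearson's r between the arrays was 0.989 and Spearman's rho 0.989, computed across genes, which are not independent replicates. The difference stayed within 0.2 log2 units for 81.3% of these genes and within 0.5 for 97.8%. Its robust SD was 0.20 in the dimmest of 4 equal level bins and 0.099 in the brightest. Probe sets of the same gene differed from each other with an SD of 0.17, over 3630 genes with at least 2 probe sets above the filter. Only 30 genes (0.323%) were at least 2-fold apart, 22 of them higher and 8 lower in the KO array. Of the 30, 5 lie on the X or Y chromosome, which leaves 20 higher and 5 lower. The counts depend on the scale, with 9 higher and 4 lower at a pseudocount of 64 and 36 and 16 at one of 1. Of 5 such genes with another probe set above the filter, 4 had the others differing in the same direction by at least 0.5 of the size, and the exception was Pgap2, whose other probe sets differed by 0.18 and 0.13.

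Among the genes named here, the largest difference in each direction was in a sex-linked transcript. Xist, the RNA that coats the inactive X chromosome of females, had a signal of 2023 in KO and 5.19 in WT. The Y-linked genes were near background in KO and clearly measured in WT. Eif2s3y, a translation initiation factor gene, read 0.27 against 254. Kdm5d, a histone demethylase gene, read 1.22 against 187, and Uty read 2.21 against 90.9. Tsix, the antisense partner of Xist, was at 3.46 and 4.61, both under the level filter, which lies at a signal of 41.5. These signals separate the arrays in the same way as the genotype labels do, and this holds beside every comparison that follows.

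Among the 42 lists other than that of Y-linked genes and Xist, the largest median difference was that of genes of the midbrain and of the isthmus, the signalling centre at the midbrain-hindbrain junction. Of 13 measured members of this list, 11 were higher in KO, 6 of them at least 2-fold, and the list median was 0.86 above WT, beyond all 10000 random lists (percentile 100, central 95% of random lists -0.11 to 0.13). Fgf17 and Fgf8, the growth factors secreted by the isthmus, read 146 against 18.8 and 103 against 18.2, differences of 2.22 and 1.80 log2 units. Pax8, Sp8 and En1, transcription factor genes of this region, were higher by 1.24, 1.24 and 1.10. En2, which is expressed across the junction, was the brightest of the higher members, at 1291 against 761 (0.75). Gbx2 (0.86), Wnt1 (0.58), Lmx1b (0.50) and Pax5 (0.41) were also higher, while Pou3f3 (-0.0043) and Lmo3 (-0.033) were level. Pax8 has another, dim probe set, with a difference of -0.0016. The list median was 0.56 at a pseudocount of 64 and 1.55 at one of 1.

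Several genes that are induced by FGF signalling and restrain it were higher in KO together with the ligands, named here for the size of their differences. Il17rd, a membrane inhibitor of FGF signalling, read 729 against 239 (1.55), Spry1 253 against 83.4 (1.43) and Spry2 308 against 113 (1.33). Etv5 and Dusp6, a transcriptional target and a phosphatase of the pathway, were higher by 0.96 and 0.94, and Spry4 by 0.89 at low signals of 27.3 and 7.30. Spry2, Etv5, Dusp6 and Spry4 lead the list of retinoic acid, FGF and Wnt signalling, in which 17 of 23 members were higher and the median was 0.28 (percentile 100). Its retinoic acid and Wnt members went both ways: Sfrp2 was higher by 0.64, Crabp2 lower by a difference of -0.10 and Wnt7a by one of -0.47. When each gene was represented by its median probe set, this list's median was 0.049 (percentile 99.27), and Spry2 took its dim probe set with a difference of -0.24.

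**Figure D1:**
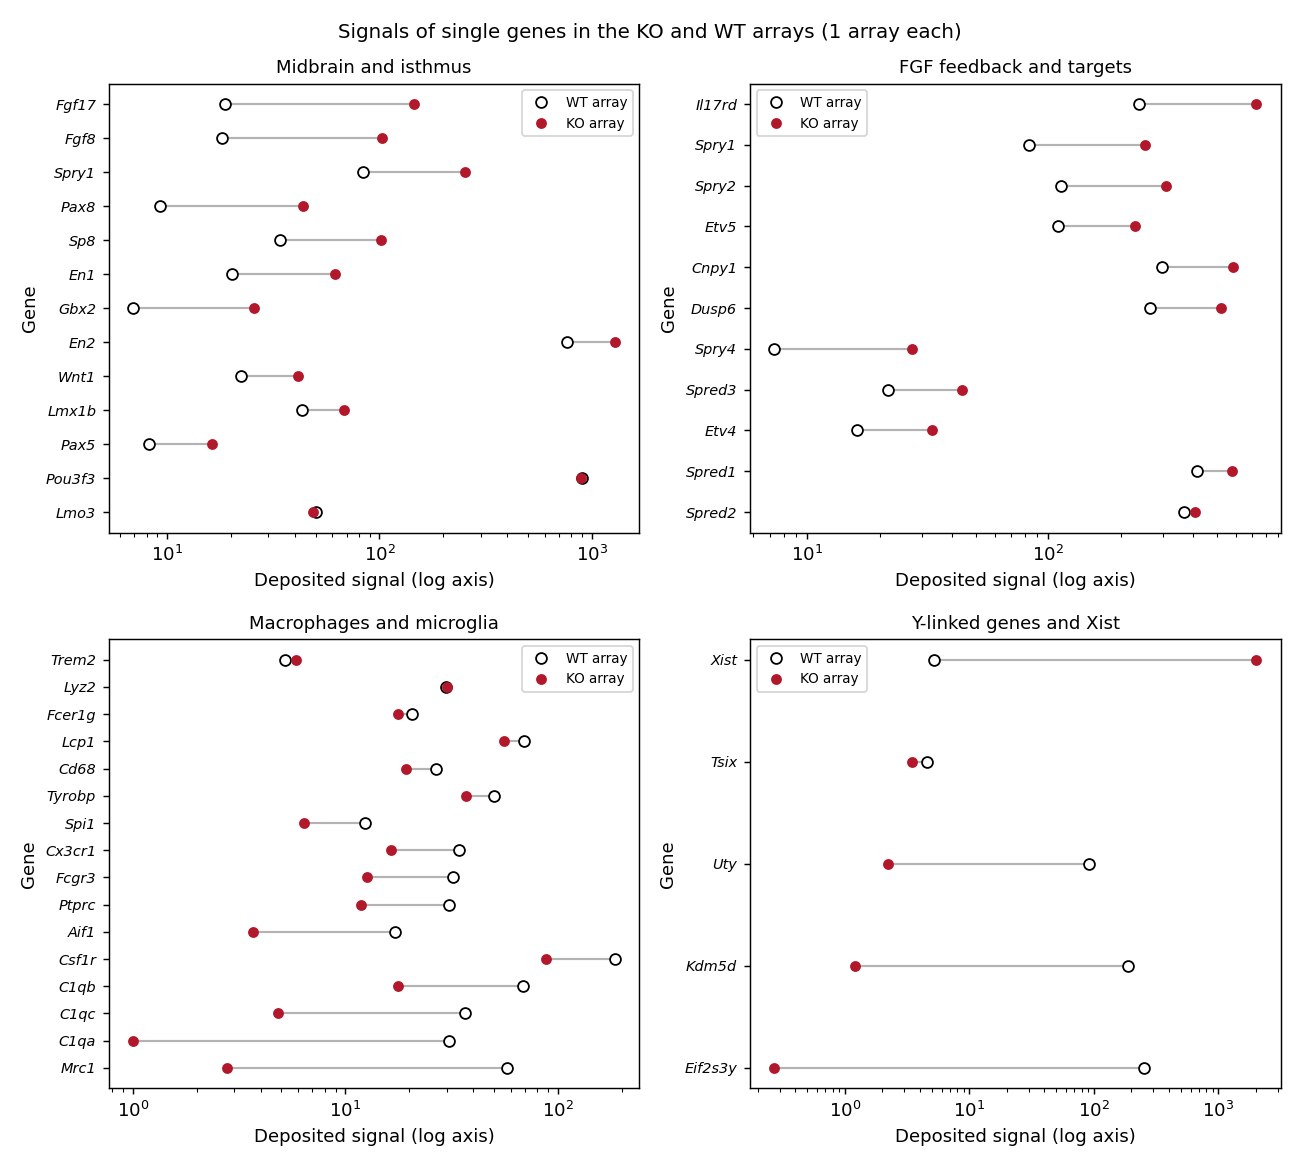
Deposited signal (log axis) of each measured member of 4 gene lists, as open points for the WT array and filled points for the KO array, 1 array each and therefore without error bars. The isthmus and FGF genes lie to the right in KO, 11 of 13 and 11 of 11, the macrophage genes to the left in 14 of 16, and Xist and the Y-linked genes Uty, Kdm5d and Eif2s3y mark the difference in sex. Unlike the other lists shown, that of FGF genes was added after a first look at the data.

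The list of dorsal neural tube genes, which also holds BMP and Wnt readouts, was higher by a smaller amount. Of 19 members, 15 were higher in KO, with a median of 0.18 (percentile 100). Msx3, a homeobox gene of the dorsal neural tube, stood far apart from the rest at 146 against 5.91 (2.88). Zic2 was next at 319 against 209 (0.57), followed by Bmp7 (0.36) and Msx1 (0.33). Of the 4 lower members, Rspo3 differed by -0.31, Lef1 by -0.22, Axin2 by -0.16 and Id3 by -0.028. The list median was 0.081 (percentile 99.29) with the mean of all probe sets of each gene.

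Macrophage and microglia markers were lower in KO. Of 16 measured members, 14 were lower, the median was -0.69 and no random list reached it (percentile 0, central 95% -0.11 to 0.14). Mrc1, the mannose receptor of tissue macrophages, read 2.76 against 57.5 (-1.97). The complement genes C1qa, C1qb and C1qc differed by -1.46, -1.33 and -1.33, and Csf1r, the receptor on which macrophages depend, read 88.1 against 187 (-0.96). Lyz2 (0.0053) and Trem2 (0.044) were level. Ly86 (-1.19), F13a1 (-1.05) and Maf (-0.80), among the 12 largest falls, are also expressed by macrophages. Only 5 of the 16 passed the level filter. The list median was -0.40 with the mean of all probe sets of each gene, -0.28 at a pseudocount of 64 and -1.05 at one of 1.

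Early neuronal genes were mostly lower by a small amount. Of 22 members, 18 were lower, with a median of -0.13 (percentile 0) and an interquartile range of -0.25 to -0.054. Dcx, a microtubule protein of migrating neurons, read 220 against 291 (-0.38), Stmn3 644 against 809 (-0.32), Tagln3 240 against 295 (-0.28) and Crmp1 415 against 505 (-0.27). Isl1 (0.29) and Elavl3 (0.28) were higher, and none was 2-fold apart. Neural progenitor genes leaned the same way, 15 of 18 lower, but their median of -0.072 lay within the random range (percentile 6.13). They stood apart after quantile normalisation (-0.059, percentile 2.16), with the mean of probe sets (-0.077, percentile 2.06) and with list means (-0.14, percentile 0.21). Proneural and Notch ligand genes had a median of 0.077 (percentile 96.1), which was -0.018 with the mean of probe sets and -0.021 with the median probe set, while list means (0.14, percentile 98.95) and a pseudocount of 64 (0.064, percentile 97.61) set the list apart as higher. Dbx1, a transcription factor gene of intermediate neural tube progenitors, was among the largest falls at 419 against 786 (-0.88).

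Interferon-responsive genes were higher in KO at low signals. Of 18 members, 14 were higher, with a median of 0.25 (percentile 99.99), but only 2 passed the level filter, and the median was 0.086 at a pseudocount of 64 and 0.65 at one of 1. Ifitm3, a membrane protein gene that restricts viral entry, read 113 against 47.2 (1.03). Oas1a (0.68), Irf7 (0.65) and Usp18 (0.49) lay below the level filter. Igtp, an interferon-inducible GTPase gene outside the list, was among the largest rises at 44.1 against 2.70 (1.68).

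Red cell genes split by level. The list median was 0.19 (percentile 100), with 11 of 15 higher, among them Alas2, the first enzyme of haem synthesis in red cells (122 against 86.6, 0.42), and Gata1 (0.33). Hba-a2 (0.67) and Epor (0.38) were below the level filter. The bright embryonic globins were slightly lower, with -0.16 for Hbb-bh1, -0.17 for Hbb-y and -0.19 for Hba-x. They kept that sign at -0.030, -0.016 and -0.057 after quantile normalisation and at -0.066, -0.070 and -0.11 after the loess. Restricted to members at or above the 75th percentile of level, the list median turned to -0.16 (percentile 2.19).

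Some lists stood apart by small shifts. Cytosolic ribosomal protein genes were lower in 16 of 17 cases, with a median of -0.16 (percentile 0). Rpl22l1, Rps2, Rps3 and Rpl22 differed by -0.27, -0.25, -0.20 and -0.19. These genes are among the brightest on the array, and after quantile normalisation the median was -0.016 (percentile 30.95) and 11 of 17 were lower. After the loess the list still stood apart, with a median of -0.064 (percentile 0.385) and 15 of 17 lower. Spiked-in control RNAs of similar brightness were also lower in KO, by differences of -0.19 and -0.16 for the CreX probe sets, and the medians over the 18 hybridisation and 24 poly-A controls were -0.076 and -0.11. Genes induced by p53 had a median of -0.10 (percentile 0.24), with 17 of 25 lower, led by Phlda3 (-0.34), Trp53i11 (-0.31), Mdm2 (-0.30) and Zmat3 (-0.26). Their median was -0.016 (percentile 39.87) among members at or above the 75th percentile of level, and -0.060 (percentile 3.17) among those passing the filter. Immediate early genes had a median of 0.19 (percentile 99.9), with 12 of 18 higher, led by Jund (0.41), Egr1 (0.38), Junb (0.37) and Klf4 (0.35), and a median of 0.00044 (percentile 72.01) with the median probe set of each gene. They no longer stood apart with the mean of probe sets either (0.085, percentile 97.39) or with list means (0.13, percentile 97.42). The pluripotency list had a median of 0.15 (percentile 99.5) from signals near background, since only 1 of its 17 members, Lin28a, passed the filter. With the mean of all probe sets of each gene it no longer stood apart (0.071, percentile 96.02), and the median was 0.056 with the median probe set, 0.049 at a pseudocount of 64 and 0.41 at one of 1. Its leading members Dppa4 (0.48), Klf4 (0.35), Utf1 (0.32) and Fgf5 (0.29) did not pass the filter. The hypoxia and glycolysis list, led by Adm (0.75), Egln3 (0.33), Pdk1 (0.29) and Pfkfb3 (0.27), had a median of 0.036 at the limit of the random range (percentile 97.535) and stood apart under 3 of 14 alternatives.

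**Figure D2:**
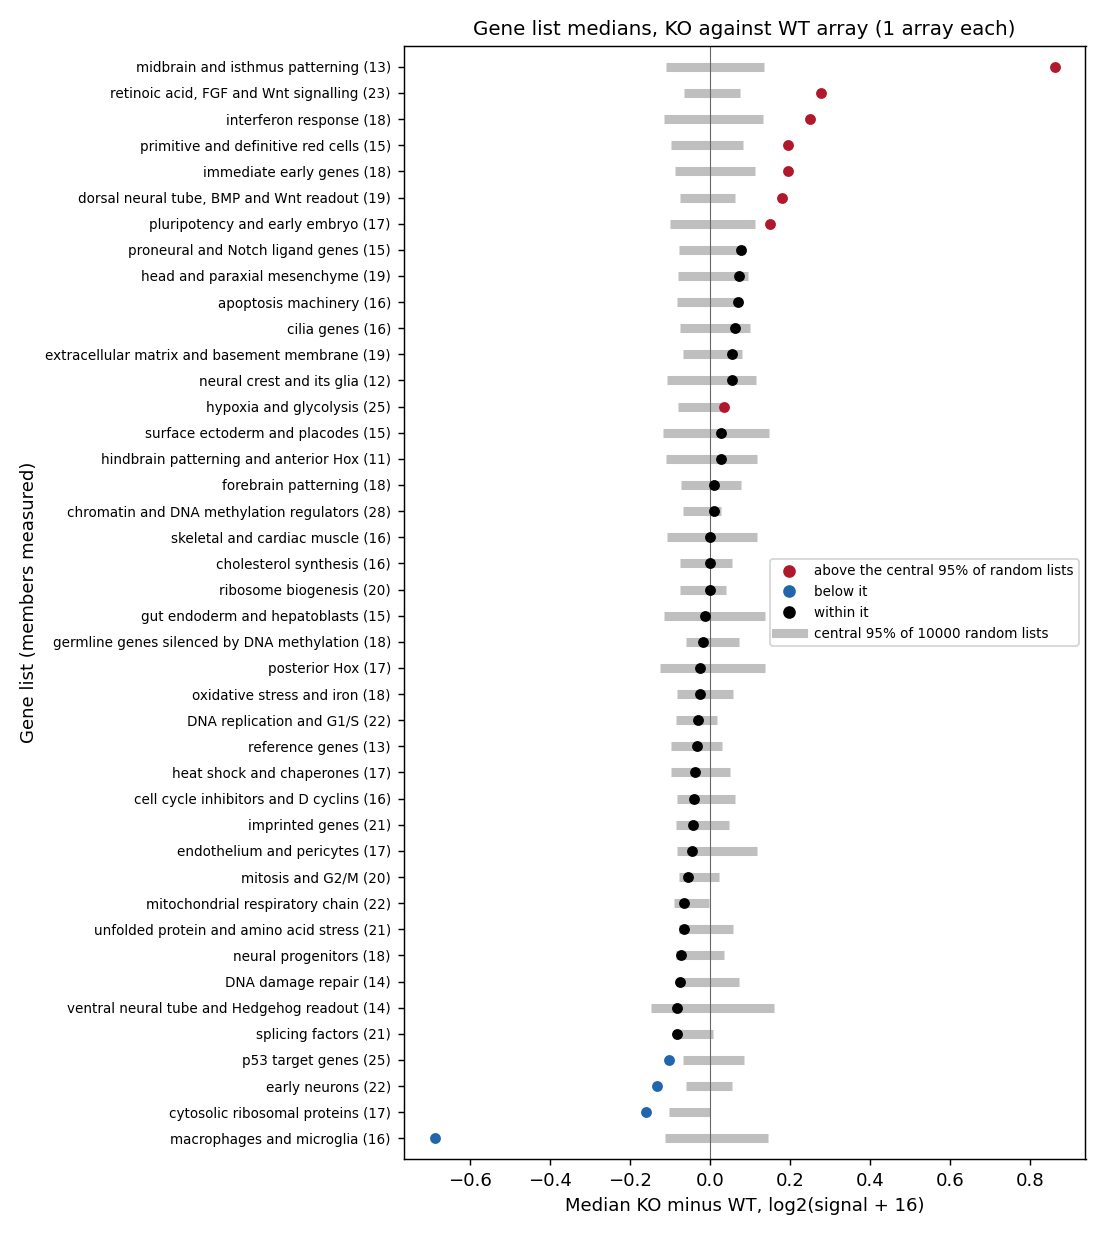
Median difference KO minus WT on the log2(signal + 16) scale for 42 gene lists (points, with the number of measured members in brackets), 1 array per group. Grey bars give the central 95% of 10000 random lists matched on level. The isthmus list (0.86) and the macrophage list (-0.69) lie farthest from it.

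Of the 43 lists, 13 stood apart, 8 higher and 5 lower, where 2.15 would be expected by chance for unrelated genes. The fifth lower list was that of the Y-linked genes and Xist, with a median of -2.55, which was -1.11 with the mean of probe sets and no longer apart with the median probe set (-0.083, percentile 17.0). The other 30 did not stand apart, which does not show that they were equal. Apoptosis genes, with a median of 0.070 (percentile 97.32), stood apart as higher under 4 alternatives, with 0.091 after quantile normalisation (percentile 99.15), 0.095 after the loess (98.88), 0.094 at the 75th-percentile filter (99.25) and 0.089 at a pseudocount of 1 (98.08). Forebrain patterning had a median of 0.011 (percentile 65.0), but only 4 of its 18 measured members passed the level filter. These 4, singled out after their values were seen, were all lower. Lhx2 read 59.4 against 104 (-0.67), and Barhl2, Otx2 and Otx1 differed by -0.63, -0.27 and -0.19. Anterior Hox and hindbrain genes (0.027), posterior Hox genes (-0.025) and ventral and Hedgehog genes (-0.081) also lay within the random range, but 0 of 11, 0 of 17 and 1 of 14 members passed the level filter. With the median probe set, the anterior Hox and hindbrain list turned to -0.13 (percentile 1.09) and the posterior Hox list was -0.16 (percentile 0.80), and the latter was -0.11 (percentile 1.39) with the mean of probe sets. Cell cycle lists were close to 0, with -0.030 for replication, of the other sign after the loess, and -0.056 for mitosis. Markers of tissues that a dissection could carry along lay within it too, with 0.055 for neural crest, 0.072 for head mesenchyme, 0.00086 for muscle, 0.028 for surface ectoderm, -0.011 for gut endoderm and -0.045 for endothelium. Of these, head mesenchyme stood apart among members passing the filter (0.20, percentile 99.85) and was -0.0018 with the median probe set. In the muscle, gut endoderm and surface ectoderm lists, 1 of 16, 2 of 15 and 6 of 15 members passed the filter. Their medians near 0 do not show that both samples held as much of these tissues. The reference genes had a median of -0.032 (percentile 55.8).

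Several of the largest single-gene differences belonged to none of the lists. Desi1, a deSUMOylating peptidase gene, read 312 against 4.98 (3.97), and its second probe set above the filter differed by 2.44. Mettl14, a subunit of the RNA m6A methyltransferase, read 42.8 against 221 (-2.02) on its single probe set. Cldn10, a tight junction gene, read 86.3 against 14.8 (1.73), Cthrc1, a secreted collagen-repeat protein gene, 106 against 21.4 (1.70), and Abcc4, a transporter gene, 220 against 81.1 (1.28). Sema3f, an axon guidance gene, was lower at 41.7 against 85.7 (-0.82).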

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

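Probe sets that name no gene here, or several, entered no comparison, yet 1313 of them passed the level filter and some differed between the arrays. Of these, 3 were at least 2-fold higher and 6 at least 2-fold lower in the KO array, against the WT array as the control. Among the 6 lower ones, 5 had a KO signal under 10 and a WT signal over 30, the farthest apart at 0.3 against 307 (-4.31). The remaining lower probe set, which carries 2 gene symbols, was bright at 1025 against 3215 (-1.63). The genes that these probe sets measure were not identified here, so sex-linked or red cell genes among them are not excluded. With 1 array per group, outliers among replicates were not looked for.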

How the results depend on the processing

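No paired analysis was possible because each group holds 1 sample, and no replicate could be left out. The isthmus, dorsal, interferon, early neuron and macrophage lists and that of retinoic acid, FGF and Wnt genes (signalling, for short) stood apart in the same direction under every alternative that gave a value (12 to 14 each). The values missing are those limited to brighter members, where too few were left. Interferon genes lacked both such settings, and the isthmus and macrophage lists lacked the 75th-percentile filter. Centring on the log2 median moved nothing, since the arrays already shared a median. Neither quantile normalisation nor the loess moved the median of the filtered genes by over 0.1 (-0.0027 and 0.0055), and both kept all 22 higher and 8 lower genes. The count of higher and lower genes was 7 and 2 with a 75th-percentile filter, 9 and 4 with a pseudocount of 64, 36 and 16 with one of 1, 77 and 55 at 1.5-fold, 10 and 5 at 1.5 log2 units, and 178 and 129 beyond 3 local robust SDs. Lower genes numbered 13 without a filter, 15 with the median probe set and 5 without X and Y, the last an alternative chosen after seeing the data. Pearson's r was 0.994 without a filter. List medians that changed were as follows. Quantile normalisation gave 0.030 for hypoxia and -0.016 for ribosomal proteins, and the loess 0.039 and -0.064. The 75th-percentile filter gave early neurons -0.191, dorsal 0.138, signalling 0.53, red cells -0.164 (reversed), hypoxia -0.0046 (reversed) and p53 -0.016. The mean of probe sets gave early neurons -0.170, isthmus 0.749, dorsal 0.081, red cells 0.135, macrophages -0.400, p53 -0.150, signalling 0.148, Y-linked and Xist -1.11, hypoxia 0.038, pluripotency 0.071 and immediate early 0.085. The median probe set, which leans towards lower values where the number of probe sets is even, gave early neurons -0.191, isthmus 0.749, dorsal 0.10, macrophages -0.622, p53 -0.167, pluripotency 0.056, signalling 0.049, hypoxia -0.051 (reversed), immediate early 0.00044, Y-linked and Xist -0.083, Spry2 -0.240 (reversed) and Pax8 -0.0016 (reversed), the last pair because the lower difference, that of a dim probe set, was taken. A pseudocount of 64 gave early neurons -0.099, isthmus 0.556, dorsal 0.143, red cells 0.139, macrophages -0.277, p53 -0.049, interferon 0.086, pluripotency 0.049, immediate early 0.076, signalling 0.131, Y-linked and Xist -1.23 and hypoxia 0.011. A pseudocount of 1 gave early neurons -0.162, isthmus 1.55, macrophages -1.05, interferon 0.647, pluripotency 0.413, immediate early 0.277, signalling 0.341 and Y-linked and Xist -4.84. The floor gave pluripotency 0.080 and hypoxia 0.036, the latter also with unmatched random lists. Means gave isthmus 0.930, dorsal 0.279, Y-linked and Xist -0.732, hypoxia 0.064 and immediate early 0.127. Filtered members gave isthmus 1.17, macrophages -0.962, immediate early 0.282, signalling 0.324, p53 -0.060 and hypoxia 0.024. This filter takes the higher array, so dim members enter through the array where they are high, which can enlarge these medians. With the mean of both arrays at or above the filter, the isthmus median was 0.99 (8 members) and the macrophage median -0.33 (3 members). Without the leading member signalling was 0.233 and hypoxia 0.024. The calls lost were those of hypoxia (11 of 14 alternatives), immediate early genes (3 of 13), p53 (2 of 14), and 1 each for ribosomal proteins, red cells, pluripotency and the Y-linked list. Except where the choice of probe set or members shows it, the cause was not tested. Of the 30 other lists, 9 stood apart under at least 1 alternative (16 of 401 values). For the 67 named genes, 510 of 627 values lay within 1 SD of the spread between probe sets, and 5 took the other sign besides the 2 reversed, all of genes under 2-fold apart. The 4 lists added later, FGF feedback genes among them, were not run under the alternatives. Lists with few members above the level filter, such as germline (0 of 18), posterior Hox (0 of 17), muscle (1 of 16), pluripotency (1 of 17) and interferon genes (2 of 18), are limited by signals near background.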

Other observations

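Of the tests in this part, the 2 of a younger embryo were set down before their values were seen, though the pluripotency list, which shares Lin28a and Lin28b with one of them, had been seen. The others, with their bounds, and the 4 added lists were chosen after a first look at the data, some of them from genes already seen. The tests of noise were replaced, and the readings for blood or vessel tissue, the passenger segment and a younger embryo in the macrophage pattern were changed, after earlier results had been seen. Genes that escape X inactivation were higher in KO in 7 of 8 cases, with a median of 0.36 (percentile 100), led by Kdm6a (332 against 196, 0.72), Mid1 (0.71), Jpx (0.47) and Eif2s3x (0.43). The 316 X-linked genes above the filter, Xist left out, had a median of 0.019. FGF feedback and target genes were higher in 11 of 11 cases, with a median of 0.94 (percentile 100), and included Cnpy1 (584 against 297, 0.94), Spred3 (0.66) and Spred1 (0.47). Fgf18, a further ligand expressed at the isthmus, read 62.6 against 21.4 (1.07). Early-stage RNA regulators were higher in 5 of 6 cases, with a median of 0.16, led by Hmga2 (1103 against 893, 0.30) and Trim71 (0.24). Later neural genes were higher in 12 of 20 cases, with a median of 0.12.

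The higher isthmus and FGF genes are a first pattern to follow up. Independent noise of low signals as the whole cause is argued against by the value that marked the isthmus list, a median of 0.86 beyond all random lists matched on level, and by 0.99 (percentile 100) for the 8 members whose mean of both arrays was at or above the level filter, and an intensity-dependent offset between arrays by the median of 0.87 after the loess (percentile 100). A larger share of junction tissue in the KO sample stays open: linear ratios of the filtered isthmus members spanned a factor of 8.01, from 0.971 for Lmo3 to 7.78 for Fgf17, but several members have other expression domains, so unequal ratios do not exclude it. In the forebrain list 4 of 18 members passed the level filter, and in the anterior Hox and hindbrain list 0 of 11. The medians of those lists therefore could not show whether both samples held the same brain regions. A younger KO embryo also stays open. Early-stage RNA regulators lay at percentile 99.9 (99.87). Later neural genes were higher rather than lower (median 0.12, percentile 98.13, and 94.95 among the 9 members passing the filter). The early neuron list, which was not part of this test, was lower in 18 of 22 cases (percentile 0). Genotype and sex may each contribute and cannot be told apart in this pair.

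The lower macrophage markers are the second pattern. Independent noise of low signals as the whole cause is argued against by the value that marked the list, a median of -0.69 where random lists matched on level held -0.11 to 0.14 in their central 95% (percentile 0), although only 3 members had a mean of both arrays at or above the level filter (median -0.33). Less blood or vessel tissue in the KO sample stays open: the red cell median lay 0.88 above the macrophage median, more than the larger interquartile range of 0.78, but only 0.53 above it among red cell genes at or above the 75th percentile of level (-0.164), and 13 of 17 endothelial genes were lower, with a median of -0.045. The globins among those bright genes were Hbb-bh1, Hbb-y and Hba-x. They shrank to -0.030, -0.016 and -0.057 after quantile normalisation and to -0.066, -0.070 and -0.11 after the loess. The bright CreX controls, unrelated to blood, differed by -0.19 and -0.16. Lower values of the size seen for these globins were thus not particular to blood genes, though neither scaling turned the sign of the globins. A bright probe set carrying 2 gene symbols, not identified here, differed by far more (1025 against 3215, -1.63). It entered no gene list, so a larger fall of a red cell gene is not excluded. For a younger KO embryo, the bound set beforehand counted a percentile of later neural genes at or over 50 against it, and the value of 98.13 met that bound; the bound was judged wrong only afterwards, because the members go both ways, with an interquartile range of -0.19 to 0.24, so this explanation is left open, as are genotype and sex, which may each contribute.

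The third pattern is a set of 15 autosomal genes at least 2-fold apart outside the isthmus, FGF and macrophage lists, among them Desi1, Mettl14, Igtp and Msx3. A chromosome segment of another strain, carried with the targeted allele, might produce such differences and would place them side by side. There were 3 neighbouring pairs within 20 measured genes of each other (Abcc4 and Cldn10, Msx3 and Ifitm3, F13a1 and Ly86), as many as in 1.32% of random sets, or 2 pairs and 4.23% without the macrophage genes F13a1 and Ly86. The pairs lie on 3 different chromosomes, so this count over the whole genome does not bear on 1 segment beside the targeted gene, which stays open. Single aberrant probe sets could not be judged, since only 2 of the genes had a second probe set above the filter and it followed in 50% of them (Desi1, not Pgap2).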
